A study of Mus musculus with 8 samples.

How the data were processed

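RNA from the frozen livers of 8 mice was measured on 4 2-colour Agilent whole-genome arrays of 1 slide, read in 1 scan, so that no comparison between slides or scans could be made. Per the labels, labelled cRNA of 1 mutant and 1 wild-type animal of the same sex was hybridised to each array with Cy3 and Cy5, arrays 1 and 2 with females and arrays 3 and 4 with males. Cy5 marked the mutant on arrays 1 and 3 and the wild type on arrays 2 and 4. The replicate number of a sample is the number of its array. Samples were grouped by the genotype and sex in the labels.

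Per the file headers, the array files were made by Agilent Feature Extraction 10.7.3.1 and hold an intensity on a linear scale for each spot and channel. These are the median pixel brightness of the spot and of its local background, and a processed signal that the software had already corrected for background, spatial trend and dye. Per the file headers, further columns are of other kinds, 0 or 1 marks per spot and channel for well above background, saturated, non-uniform and population outlier. The deposited series table holds log2 values of 55681 probes. Its values look like log2 processed signals with equal column means, each probe centred on its median over the 8 samples. This reading was taken from the values and is not settled. Such centring alone would shift all genes of a comparison alike. Yet 0 genes differed by sex with the series table and 31 with processed signals, so the values differ in some further way that was not worked out. Its medians per sample were −0.0136, −0.00537, −0.00754, −0.00392, −0.000942, 0.00951, 0.0099 and 0.015 for wild type 1, mutant 1, mutant 2, wild type 2, wild type 3, mutant 3, mutant 4 and wild type 4. Of the array files, 68 columns of per-sample values were not used here. A mean signal had been chosen before the data were examined, but the array files give medians only, so the median signal was used.

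Each array has 62976 spots, of which 59305 are not controls and stand for 55681 probes. Symbols came from matching the RefSeq accessions of the probes, which named 27656 probes with 20972 symbols. There were 359 NM_ accessions without a match and 16194 probes named by chromosome region only. Well above background were 42.97%, 43.95%, 42.23% and 43.79% of spots in wild type 1, mutant 1, mutant 2 and wild type 2, and 36.81%, 37.87%, 36.98% and 36.78% in wild type 3, mutant 3, mutant 4 and wild type 4. Between 0 and 40 spots per sample were saturated. No 2 samples had identical raw signals (0 pairs).

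Signals were background-corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with the package data.table (version 1.17.8). Marked spots were left out, control spots had no weight, and spots of a probe were averaged. Probes well above background in at least 4 of the 8 samples were kept (22031), and each gene was represented by its probe with the highest mean intensity. This gave 17531 genes or unnamed transcripts, 11852 with a symbol and 5679 without. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

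The log2 ratios of mutant over wild type were fitted with limma with a coefficient for genotype and one for dye, empirical Bayes moderation and Benjamini-Hochberg adjustment, with 0.05 as the threshold. The difference of the genotype effect between sexes used the same ratios with a coefficient per sex, and leaves 1 residual degree of freedom. Males and females were never on the same array. They were compared in a separate-channel fit after Aquantile normalization between arrays, with genotype-by-sex groups, dye and a within-spot correlation of 0.794. Across genes, which are not independent replicates, the deviations from the genotype mean of samples with the same replicate number correlated at 0.685, 0.176, 0.56 and 0.646. Samples of the same sex with other numbers also correlated (0.74, 0.237, 0.509 and 0.471). The numbers name a shared array, so they pair the samples and the array is the block in the design.

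Gene lists were fixed before the data were examined, as were the rule for named genes, the tests and most alternatives. Of 42 lists, 40 had 3 or more tested members. The list of mitochondrially encoded transcripts had 0 tested and that of skeletal muscle and heart 2. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and, for genotype, with fry, a rotation test of whether the genes of a list move on balance one way. Adjustment was over the 40 lists. For sex, camera was run on the moderated statistics of the separate-channel fit.

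Genes were named by a rule. For genotype these were Pus1, then the 12 with the highest and the 12 with the lowest change among those past the threshold with 1 sign on all 4 arrays. Where fewer passed, the genes with the smallest p in each direction and 1 sign on all 4 arrays filled the 12, given as values that did not pass. For each list the 2 to 4 members with the smallest p were taken. For sex these were Xist, the Y-linked genes and the 8 largest differences in each direction with all males on one side of all females. For the difference between sexes these were the 3 with the smallest p in each direction. Some genes that the rule took are not described here and were not replaced, which leaves 21 besides Pus1 for genotype. Exceptions chosen after their values were seen are the genes named near Pus1, the single clock genes, Igfbp1, Saa1, and genes named because an alternative called them.

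Bounds come from levels normalized over all probes, and the sex fit from levels normalized over the genes tested, so a bound can lie above the fitted fold. Where it did, the fitted fold is given instead. A bound, written as at least so many fold, is otherwise given where no sample of a group had the probe well above background. It is the mean of the bright group over the mean of the dim group, with each dim sample set to the higher of its own signal and the lowest signal well above background in that channel, after normalization. The genes near Pus1 were taken from positions in the mouse assembly GRCm38.p6, of which only gene names and order are used, since the array files name an older assembly. They lie within 20 Mb of Pus1 on chromosome 5, and Pus1 itself was left out. Their share was compared with that of all other positioned genes by a two-sided Fisher's exact test.

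The fits were tested on simulated data with 22031 genes, of which 200 were changed for each of genotype, sex and the difference between sexes. The changed genes were drawn from the brighter probes, so the rates do not cover dim genes, such as Pus1 in mutants. Of genes changed 1.5-fold, 2-fold and 4-fold, the genotype fit called 43.3%, 95.5% and 100%, with 6 false calls, and 4.58% of unchanged genes had a p under 0.05. The fit of the difference between sexes called 3.03%, 32.8% and 100%, with 35 false calls, and the sex fit 0%, 3.03% and 85.1%, with 0 false calls. The separate-channel fit of genotype made 508 false calls, and 19.8% of its unchanged genes had a p under 0.05. With the preset correlation 3 of 100 unshifted lists had a camera p under 0.05, and with an estimated one 0. A truly shifted list had a p of 2.71e-30 with the preset correlation and 0.00634 with an estimated one. The simulated genes were independent, so this does not test the preset value on real lists. Their estimates could be far higher, such as 0.869 for interferon response genes by genotype. The simulation was run after the real fits and was revised once after its first output, when a constant spread was replaced by each probe's moderated spread. Moderated spreads are shrunken, so real recovery is probably lower.

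Alternatives were no background correction, offset 16, processed signals, the values of the series table, median centring, no filter, a filter on all 8 samples, no dye term, other ways to treat the probes of a gene, an intensity trend with a robust prior, quantile normalization, other blocks, wild types only, and each array left out in turn. With an array left out, the sex fit kept the correlation of 0.794, since it could not be estimated from 3 arrays. Added after the data were seen were an additive fit with a random block, the estimated correlation and left-out arrays for sex lists, lists without genes near Pus1, and the smaller threshold near Pus1 for other windows and left-out arrays.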

Results

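Liver gene expression was compared between mice homozygous for a mutant Pus1 allele and wild-type mice. Pus1 encodes pseudouridine synthase 1, an enzyme that converts uridine to pseudouridine in tRNAs and other RNAs of the nucleus, the cytosol and the mitochondria. The series was set up to ask which liver transcripts differ when this enzyme is lost. The samples were the livers of 4 mutant and 4 wild-type animals aged 14 to 16 weeks, with 2 females and 2 males of each genotype, on a C57BL/6J background after 5 generations of backcrossing. Each of 4 2-colour arrays carried 1 mutant and 1 wild-type liver of the same sex, and the dyes were swapped between both arrays of a sex. Of 59305 non-control spots, between 36.8% and 44.0% were well above background in a sample. The 4 female samples lay between 42.2% and 44.0% and the 4 male samples between 36.8% and 37.9%. After the filter on dim probes, 17531 genes or unnamed transcripts were tested, of which 11852 carried a gene symbol. The number of arrays limits the precision of every value.

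The first comparison was of the targeted gene itself. The 1 Pus1 probe on the array (transcript NM_001025561) read 8.66 ± 0.24 (SD, n = 4) on the log2 scale in wild-type livers and 6.63 ± 0.22 (SD, n = 4) in mutant livers. It was well above background in 4 of 4 wild types and in 0 of 4 mutants. By the measured signals Pus1 was 4.10-fold lower in mutants. The bound described above equalled this fold, so it adds no separate lower limit. The log2 ratio of the measured signals, those of mutants being not well above background, was −2.03 ± 0.11 (SE), and the 4 arrays gave −2.14, −2.11, −1.82 and −2.07, a spread of 0.14 (SD). The adjusted p over all 17531 tests was 0.0567, which missed the threshold of 0.05, and it was 3.23e-05 when adjusted over the list alone, that is the 10 pseudouridine synthases tested. Where the probe lies relative to the altered part of the gene is not given in the sources used here. Over the alternatives run, those with an array left out included, the adjusted p ran from 0.00483 to 0.464. The log2 ratio ran from −1.85 to −4.37, the latter with the scanner software's processed signals. With single arrays left out, Pus1 passed without array 4 (adjusted p = 0.0104) and did not without arrays 1, 2 or 3. Each of these fits leaves 1 array alone in its dye orientation, and without array 4 that is array 2.

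**Figure D1:**
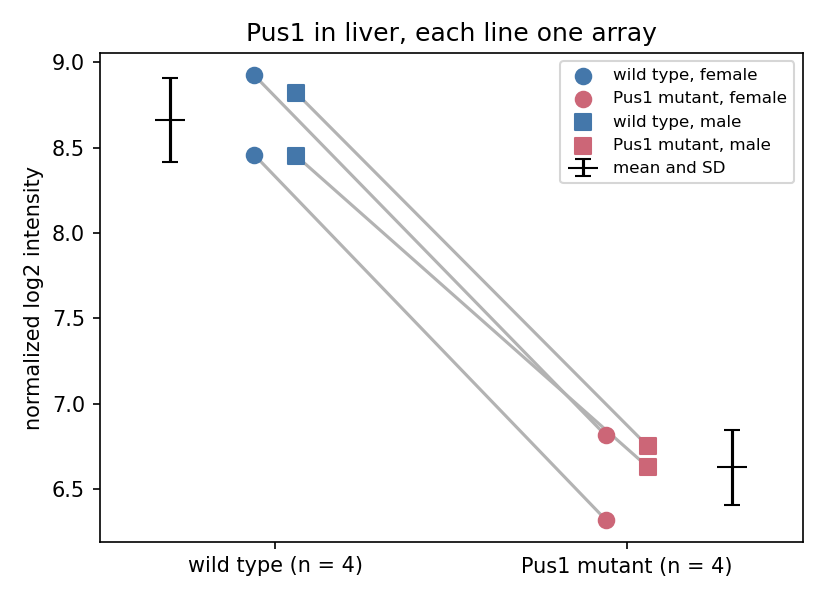
Normalized log2 intensity of the Pus1 probe in each liver. Circles are females, squares are males, grey lines join both samples of one array, and black bars give the mean and SD of 4 samples per genotype. The 4 wild-type livers lie between 8.45 and 8.92 and the 4 mutant livers, none well above background, between 6.32 and 6.81.

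The relatives of Pus1 and the rest of the tRNA machinery showed small ratios. Of 10 pseudouridine synthases tested, 6 were higher and 4, Pus1 among them, were lower in mutants, and no member besides Pus1 passed even over the list alone. Rpusd4, a mitochondrial pseudouridine synthase, had a log2 ratio of 0.31 ± 0.17 (SE), and Trub2, another, 0.23 ± 0.16 (SE). The list as a whole did not pass (median log2 ratio 0.03, mean −0.13, camera adjusted p = 0.911), the mean being drawn below 0 by Pus1. The 31 tested enzymes that modify or process tRNA in other ways had a median of 0.03 (adjusted p = 0.547). Among aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 11 of 15 mitochondrial members were higher, with a median of 0.08 (adjusted p = 0.166), and 15 of 19 cytosolic members were higher, with a median of 0.11 (adjusted p = 0.147). No tRNA-modifying enzyme or synthetase of these last 3 lists passed, over all genes or over its list alone.

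No gene differed between genotypes at an adjusted p under 0.05 in the limma fit of the 4 ratios. At an unadjusted p under 0.05 there were 1561 (832 higher and 729 lower in mutants), where 877 would be expected with no difference. Exchanging the genotype labels on some arrays, where the fit could be run, gave 55, 506, 412, 187 and 205 such genes. With the labels of array 4 alone exchanged it gave 4529, more than the real grouping. The count of 1561 against 877 therefore does not by itself show an effect of genotype. Since no gene passed, the named genes below are given as values that did not pass, with an adjusted p of 0.263 for Gpat3 and 0.541 for each of the others. Without the array of mutant and wild-type male 4 the count was 1490 (614 higher and 876 lower), and without any other array it was 0. A fit of the 8 single channels with the array as a random block called 1514 (704 higher and 810 lower), and on simulated signals that fit gave 19.8% of unchanged genes a p under 0.05.

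Named next are 12 of the genes with the smallest p among those higher in mutants on all 4 arrays, none of which passed. Birc5, a survivin that guides chromosome segregation, was 3.14-fold higher (log2 1.65 ± 0.24 SE). The mitotic kinase Aurka was 2.38-fold higher (log2 1.25 ± 0.16 SE), but well above background in only 1 of 4 wild types. Its spindle partner Tpx2, well above background in 4 of 4 mutants and 0 of 4 wild types, was at least 1.52-fold higher. Tpx2 had a log2 ratio of −0.07 when dim probes were kept and another Tpx2 probe was used. The kinetochore gene Spc24 (1.63-fold), the tubulin gene Tubb6 (2.01-fold), the histone gene H2ac4 (1.98-fold) and the long non-coding RNA Lockd (2.54-fold) were also higher. Gpat3, an acyltransferase of triglyceride synthesis, was 2.59-fold higher, with log2 ratios from 0.51 to 2.11 over the arrays. Marco, a scavenger receptor of macrophages, was 1.64-fold higher, but read −0.05 on the log2 scale in the values of the deposited series table. Gstm2, a glutathione S-transferase, was 1.61-fold higher with a spread of 0.10 (SD) over arrays. Oas1a, an interferon-induced sensor of double-stranded RNA, was 2.23-fold higher, and Vsig10 was 1.74-fold higher. Lockd and Vsig10 were well above background in 3 of 4 wild types. With the scanner software's processed signals the log2 ratios of Aurka, Tpx2, Lockd and Vsig10 were 2.51, 2.55, 2.54 and 1.51, still without passing (adjusted p = 0.371 to 0.498). In the values of the series table Gpat3, Birc5 and Oas1a were at 0.64, 0.95 and 0.37.

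Of the genes with the smallest p among those lower in mutants, 9 are named here, and none of them passed. Camk2b, a subunit of a calcium-dependent kinase, was 1.93-fold lower (log2 −0.95 ± 0.17 SE), Syt1, a calcium sensor of vesicle release, 1.66-fold lower, and the lipid droplet protein gene Plin4 1.65-fold lower. The Syt1 fold leans on array 2, with a log2 ratio of −1.49 there and −0.59 to −0.42 on the other arrays. Wild-type female 2 of that array read 10.8 for Syt1, within the male range of 10.5 to 11.1. The other females read 9.08 to 9.51. The sulfate transporter gene Slc26a1 was 1.58-fold lower, Thap6 1.54-fold, the ATP-gated channel gene P2rx7 1.54-fold, and Fgfrl1 1.52-fold. P2rx7 was at −1.34 on the log2 scale with processed signals (adjusted p = 0.498), against −0.62, and Camk2b at −0.19 in the values of the series table. Of the mutants, 2 of 4 were well above background for P2rx7 and 3 of 4 for Dnah6. Dnah6, a dynein gene, was 1.38-fold lower and Eif5, a translation initiation factor, 1.36-fold lower. Of the 21 genes named by genotype besides Pus1, 7 lie within 20 Mb of Pus1 in the mouse assembly GRCm38.p6, namely Gpat3, Vsig10, Oas1a, P2rx7, Slc26a1, Thap6 and Fgfrl1.

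Gene lists chosen before the data were examined were then tested for a shift by genotype, and 7 of 40 were shifted with a preset correlation between genes of 0.01, all of them higher in mutants. Every one of these calls was lost when the correlation was estimated from the arrays (adjusted p = 0.699 for each list with an estimated correlation), and 0 lists passed the rotation test fry. With 4 arrays the estimated version has little power, so this loss alone does not show that the lists were unshifted. In the simulation it gave a truly shifted list a camera p of 0.00634, against 2.71e-30 with the preset correlation. For antioxidant enzymes the camera p rose from 5.5e-07 to 0.0302, although the estimate of −0.00607 was under the preset value. The count was 14 without array 1 and 12 without array 3.

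The cell cycle list had the largest median. Its 21 tested members had a median log2 ratio of 0.77 (camera adjusted p = 1.76e-14), with array medians of 0.54, 0.81, 1.15 and 0.51. Of these members, 19 were higher in mutants, 15 were higher on all 4 arrays, 0 passed over all genes tested and 15 passed when adjusted over the list alone. Examples are Cdc20, an activator of the complex that ends mitosis (log2 1.97 ± 0.32 SE), and Ccna2, a cyclin of DNA synthesis and mitosis (0.96 ± 0.16 SE, well above background in 3 of 4 wild types), beside Aurka and Birc5.

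Markers of Kupffer cells, the resident macrophages of the liver, were higher together. The 15 tested markers had a median log2 ratio of 0.65 (camera adjusted p = 4.42e-12), with array medians of 0.49, 1.12, 0.44 and 0.42. All 15 were higher in mutants, 13 on all 4 arrays, and 12 passed when adjusted over the list alone, against 0 over all genes. Lyz1, a lysozyme gene, had a log2 ratio of 0.89 ± 0.16 (SE), Timd4, a receptor for dying cells that was well above background in 3 of 4 wild types, 0.70 ± 0.14 (SE) and Cd5l 0.74 ± 0.16 (SE). Markers of other cell types did not pass. Neutrophil markers had a median of 0.53 (6 tested, adjusted p = 0.0624), lymphocyte markers 0.16 (10 tested, adjusted p = 0.166), endothelial markers −0.07 (13 tested, adjusted p = 0.549), stellate cell and fibrosis genes 0.06 (13 tested, adjusted p = 0.362) and cholangiocyte markers −0.03 (7 tested, adjusted p = 0.407).

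Interferon response genes were higher in mutants, by more on the arrays of females. All 24 tested members had a fitted log2 ratio above 0, with a median of 0.56 (camera adjusted p = 4.82e-10), but the array medians were 0.68 and 1.52 for the females and 0.20 and −0.05 for the males. A test of that difference between the sexes, chosen after the values were seen, gave an adjusted p of 1.39e-24 with the preset correlation. An estimated correlation was not run for that test, and it ended the call of this list by genotype (estimate 0.869, adjusted p = 0.699). Of the members, 5 were higher on all 4 arrays, and 1, Oas1a, passed when adjusted over the list alone, against 0 over all genes. Usp18, a protease that removes the ubiquitin-like protein made in the interferon response, had a log2 ratio of 1.11 ± 0.38 (SE), Gbp3 0.82 ± 0.26 (SE) and Bst2, which tethers budding viruses, 0.54 ± 0.19 (SE). Of the 24 members, 6 lie within 20 Mb of Pus1 (Oasl1, Oasl2, Oas1a, Oas2, Cxcl9 and Cxcl10), and without them the adjusted p was 8.97e-08.

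The other 4 shifted lists moved by smaller amounts. Antioxidant enzymes and targets of the stress regulator NRF2 had a median log2 ratio of 0.21 (camera adjusted p = 5.5e-06), and 23 of 27 were higher. Gstm2 and Gstm3, glutathione S-transferases, passed when adjusted over the list alone, and Gstm3 had a log2 ratio of 0.83 ± 0.17 (SE). Genes of amino acid and urea metabolism had a median of 0.18 (adjusted p = 7.24e-05), with 25 of 31 higher. Ass1 (0.39 ± 0.11 SE), Nags (0.43 ± 0.13 SE) and Asl (0.44 ± 0.15 SE), all of the urea cycle, had the smallest p there. Nuclear-encoded subunits of oxidative phosphorylation, the mitochondrial chain that makes ATP, had a median of 0.10 (adjusted p = 1.58e-05), with 62 of 74 higher and 14 higher on all 4 arrays. The medians were 0.16 and 0.13 on the arrays of females and −0.04 and 0.08 on those of males. Ndufs8 of complex I (0.56 ± 0.14 SE) and Cyc1 of complex III (0.51 ± 0.16 SE) had the smallest p. Mitochondrial ribosomal proteins had medians of 0.15 and 0.31 on the arrays of females and −0.04 and 0.02 on those of males. Their fitted ratios had a median of 0.12 (adjusted p = 0.000332), with 59 of 75 higher. Mrpl42 (0.39 ± 0.12 SE) and Mrpl46 (0.51 ± 0.17 SE) were among them. Without array 1 the call ended for oxidative phosphorylation (adjusted p = 0.0906) and for mitochondrial ribosomal proteins (0.0744), and the latter also without array 2 (0.0652). No member of these 3 lists of metabolism and mitochondria passed over its list alone.

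**Figure D2:**
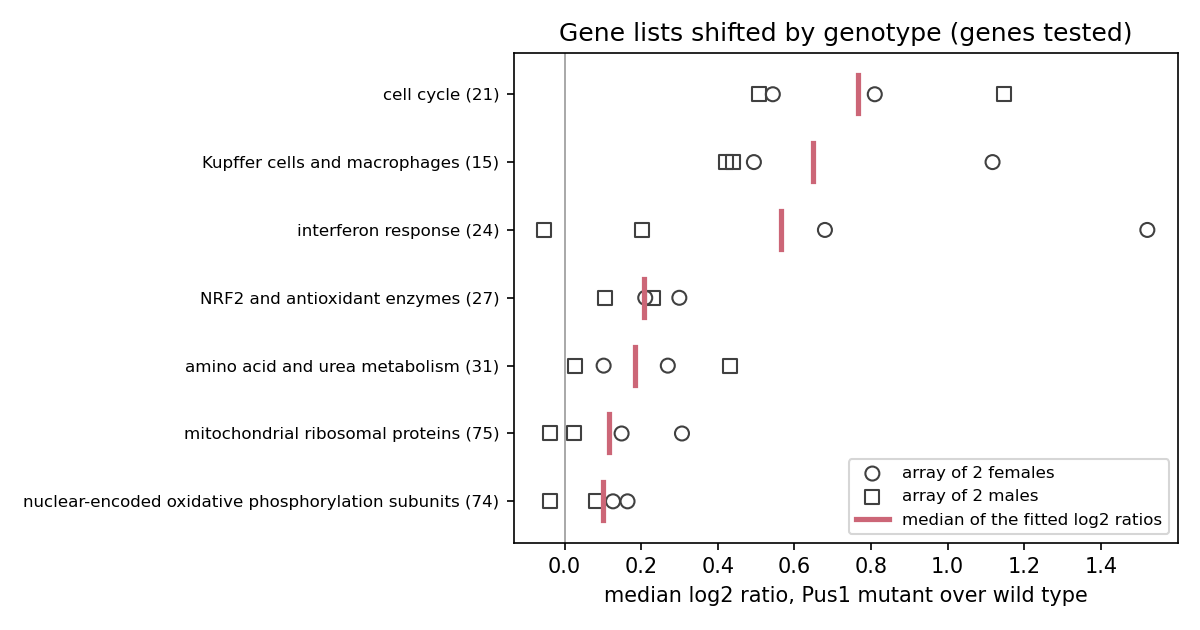
Median log2 ratio, Pus1 mutant over wild type, of the 7 gene lists shifted by genotype with a preset correlation, with the number of genes tested in brackets. Open circles are the 2 arrays of females, squares the 2 arrays of males, and red bars the median of the fitted ratios. Cell cycle genes lie above 0 on all 4 arrays, between 0.51 and 1.15, whereas interferon response genes run from −0.05 to 1.52.

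Genes that neighbour Pus1 were then compared with the rest of the genome, since donor sequence beside a targeted allele can pass through backcrossing with it. With the adjusted threshold there was nothing to compare, since 0 of 277 tested genes within 20 Mb of Pus1 and 0 of 11576 elsewhere passed. At an unadjusted p under 0.01, 22 of the 277 (7.94%) were found near Pus1 and 126 of 11576 (1.09%) elsewhere (odds ratio 7.84, two-sided Fisher's exact test, p = 3.85e-12). Of these 22, 14 were higher and 8 lower in mutants. None of the 22 passed over all genes. They included Kdm2b, a histone demethylase gene (log2 1.45), Gpat3 (1.37), the lipid droplet enzyme gene Hsd17b13 (0.51) and its neighbour Hsd17b11 (0.67), and Ulk1, a kinase that starts autophagy (−0.54). Over the whole of chromosome 5, which carries Pus1, there were 22 of 753, so every one lay within 20 Mb. Without arrays 1, 2, 3 and 4 in turn, 8, 20, 6 and 56 genes were found near Pus1, with p of 9.12e-05, 4.38e-12, 0.0071 and 1.31e-05. These are 2.89%, 7.22%, 2.17% and 20.2% of the genes near Pus1, against 0.467%, 0.865%, 0.579% and 11.1% elsewhere.

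**Figure D3:**
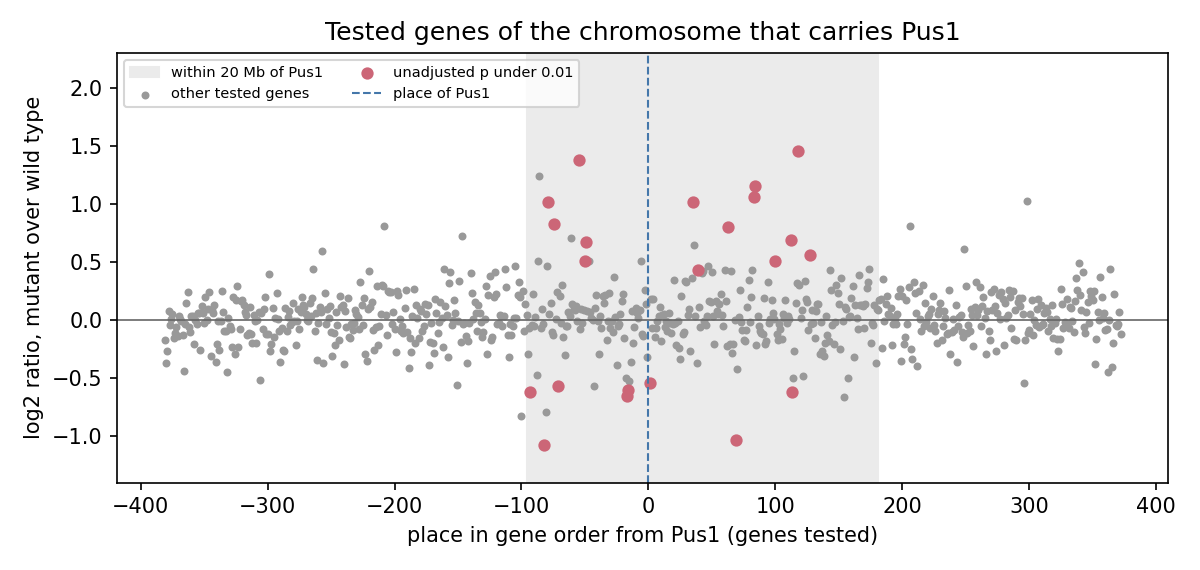
Log2 ratio, Pus1 mutant over wild type, of each tested gene of chromosome 5, against its place in the gene order counted from Pus1. Red points have an unadjusted p under 0.01, grey points do not, and the shaded band holds the genes within 20 Mb of Pus1 in assembly GRCm38.p6. All 22 red points lie in the shaded band, with 14 above 0 and 8 below.

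Male and female livers were compared next, which checks the sex labels and gives the size of a known difference. Both Y-linked genes measured, Eif2s3y and Ddx3y, were well above background in 4 of 4 males and 0 of 4 females, and were at least 14.9-fold and 11.6-fold higher in males (adjusted p = 0.00666 and 0.00719). Xist, the RNA that silences an X chromosome, was at least 8.03-fold higher in females, with 9.45 ± 0.70 (SD, n = 4) against 6.33 ± 0.10 (SD, n = 4), but did not pass (adjusted p = 0.103). In all, 37 genes differed, 18 higher in males and 19 higher in females, with 2842 at an unadjusted p under 0.05.

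Genes higher in males were led by cytochromes of the Cyp4a12 family, which hydroxylate fatty acids. Cyp4a12b was at least 135-fold higher (adjusted p = 0.000279) and Cyp4a12a 126-fold (log2 6.97 ± 0.13 SE, adjusted p = 0.00017), the latter well above background in 1 of 4 females. Nat8 (23.8-fold), Tff3 (22.9-fold), Cyp7b1 of bile acid synthesis (9.90-fold), the complement gene C6 (9.05-fold), Alas2, the heme synthesis enzyme of red cell precursors (8.13-fold), and Gstp1 (7.21-fold) were also higher. Genes higher in females were led by the sulfotransferase Sult2a2 (at least 331-fold, adjusted p = 0.00911) and the cytochromes Cyp3a44 (at least 117-fold) and Cyp2b13 (108-fold). Sult3a1 (31.7-fold), the organic anion transporter gene Slc22a26 (28.4-fold), Prom1 (11.3-fold) and Cyp2b9 (9.85-fold) were higher as well. Cyp2b13, Sult3a1, Slc22a26 and Cyp2b9 were well above background in 0 of 4 males. Their bounds lay above these fitted folds and are not given. Tff3 was well above background in 3 of 4 females and Prom1 in 2 of 4 males. Of the genes named, C6 did not pass without array 3 or 4 (adjusted p = 0.0522 and 0.0689) or with the filter on all 8 samples (0.0561), nor Tff3 without array 4 (0.0529). With processed signals Tff3, C6, Sult3a1 and Prom1 did not pass (0.128, 0.0868, 0.0764 and 0.0783), with wild types alone Cyp7b1 and C6 did not (0.052 and 0.101), and none passed with the values of the deposited series table (0.528 for each). For each gene of this paragraph all 4 samples of one sex lay above all 4 of the other, as the rule for naming them required.

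Of the gene lists, 17 of 40 differed by sex with the preset correlation, 3 higher in males and 14 higher in females. None did with a correlation estimated from the samples, where the smallest adjusted p = 0.1. That version has little power here. For female-biased liver genes the estimate was 0.00828, under the preset value, yet the camera p rose from 9.73e-119 to 0.00251. Female-biased liver genes had a median log2 difference, male minus female, of −2.76 (camera adjusted p = 3.89e-117), with 25 of 26 lower in males, 10 called over all genes and 17 when adjusted over the list alone. Male-biased liver genes had a median of 1.58 (adjusted p = 7.32e-72), with 31 of 32 higher in males, 6 called over all genes and 21 over the list alone. Xenobiotic metabolism genes were higher in females (median −0.79, adjusted p = 4.04e-42), with 4 called (Cyp2b13, Cyp3a44, Cyp2b9 and Cyp3a16, the last at −1.78 ± 0.14 SE) and 12 over the list alone. Cholesterol synthesis and uptake genes were higher in females in 24 of 25 cases (median −0.90, adjusted p = 4.2e-08), with 0 called and 9 over the list alone. Cyp51, a demethylase of sterol synthesis, was at −1.35 ± 0.28 (SE) and Hmgcs1, an enzyme of the mevalonate pathway, at −1.63 ± 0.34 (SE). Interferon response genes were higher in females as well (median −0.84, adjusted p = 7.24e-07), in 24 of 24, with 0 called and 3 over the list alone. Genes of red blood cells and blood content were higher in males (median 1.92, adjusted p = 7.85e-13), with 10 of 11 higher in males, 1 called (Alas2) and 8 over the list alone. The anion exchanger gene Slc4a1 was at 1.37 ± 0.17 (SE) and the globin gene Hbb-bt at 2.28 ± 0.47 (SE). The Y-linked and X-inactivation list also differed (adjusted p = 1.19e-12). Most females also stood apart from the males in clock genes and Igfbp1, as given next. A list that follows the same pattern cannot be assigned to sex alone.

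Several transcripts of the liver clock stood at other levels in males than in 3 of 4 females, although none of the 17 clock genes tested was called by sex. Dbp, a transcription factor whose level swings widely over the day, read 8.10, 8.04 and 9.71 in wild-type female 1, mutant female 1 and mutant female 2, but 14.8 in wild-type female 2, within the male range of 13.5 to 14.8. Tef and Usp2 followed it, with 14.9 and 12.3 in wild-type female 2 against at most 11.6 and 8.36 in the other females. Arntl, whose phase is opposite, was not among the 17, since it was well above background in fewer than 4 of the 8 samples. Its brightest probe read 6.14 in wild-type female 2, between 9.93 and 10.1 in the other females and between 6.69 and 7.19 in males. Its low readings are therefore limited by the background. The circadian list did not pass by sex (median 0.41, adjusted p = 0.662), but passed without array 2, higher in males (0.000284), and did not without arrays 1, 3 or 4 (0.212, 0.903 and 0.205). Igfbp1, a gene that rises in fasting and was chosen after its values were seen, read 12.4 in wild-type female 2, 17.1 to 17.9 in the other females and 12.2 to 13.7 in males. This female shares array 2 with mutant female 2. Without that array 1197 genes differed by sex, among them all 37, and without arrays 1, 3 or 4 the counts were 165, 86 and 65, among them 37, 29 and 28 of the 37. Without array 2 every remaining female stood apart from the males in these transcripts. Sex and that state therefore cannot be told apart in the 1197.

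**Figure D4:**
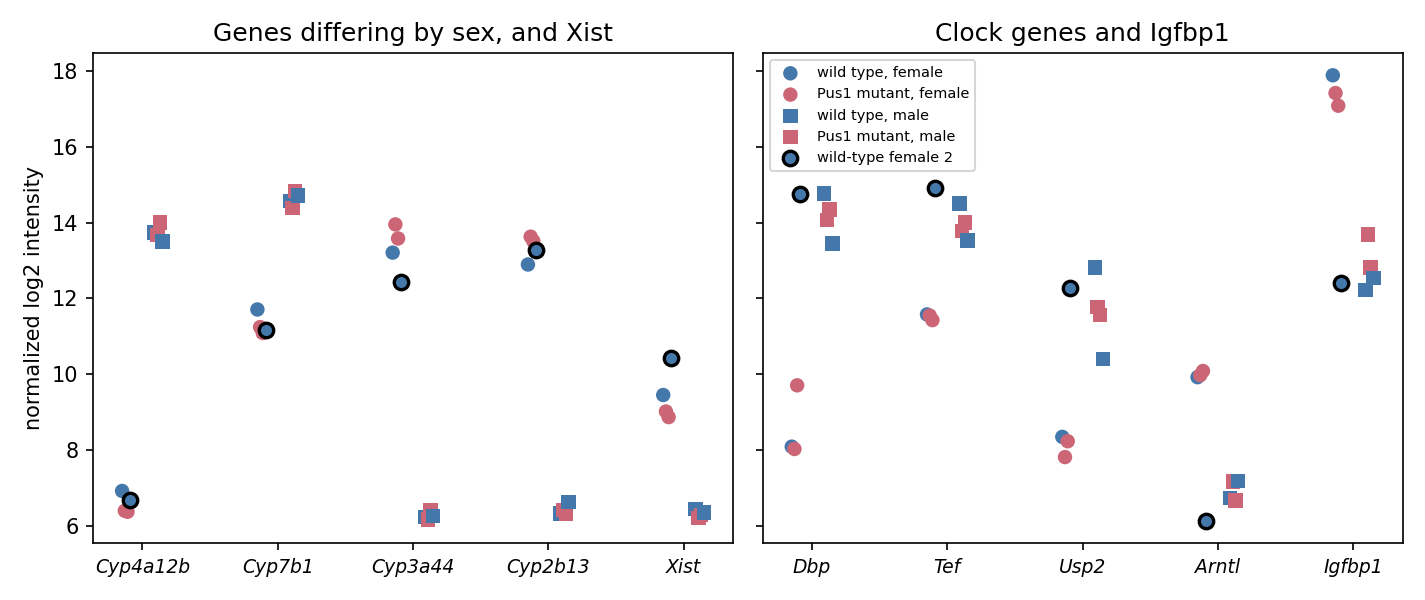
Normalized log2 intensity per liver of 4 genes that differed by sex and Xist (left) and of 4 clock genes and Igfbp1 (right). Circles are females, squares males, blue wild type and red Pus1 mutant, and wild-type female 2 has a black outline. Arntl did not pass the filter on dim probes and was not tested. That sample lies with the other females in the left plot, for example at 13.3 for Cyp2b13, and with the males in the right plot, for example at 14.8 for Dbp.

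The last comparison asked whether the effect of genotype differed between males and females. No gene passed (limma, smallest adjusted p = 0.824), with 1022 at an unadjusted p under 0.05 where 877 would be expected, and none passed in 8 other ways of processing the arrays. This fit leaves 1 residual degree of freedom. The genes with the smallest p are given as values. The clock gene Per1 had a log2 ratio of −1.61 in females and 0.38 in males, the growth factor receptor Egfr −1.74 and 0.24, and Ugt1a10, an enzyme of glucuronidation, −1.50 and 0.09. In the other direction, Akr1c18, which breaks down progesterone, had 1.90 in females and −0.06 in males, Prom1 1.54 and 0.09, and the cytokine gene Il1b 1.78 and 0.19. Both female arrays had ratios of 1 sign for each of these genes, such as −1.74 and −1.49 for Per1 and 2.06 and 1.74 for Akr1c18. The arrays were furthest apart for Il1b, with 0.71 and 2.86 in females and −0.65 and 1.03 in males.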

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

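Chosen after the results were seen were the tests of the hepatocyte share, the sex label, the hybridisation and labelling, the time of day, the donor sequence and the probe mismatch, and the tests of list effects by sex. The tests against random lists, of other genome windows and of other splits of the samples were written before their results were seen.

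Cell cycle and Kupffer cell genes were higher in mutants with the preset correlation (median log2 ratios 0.77 and 0.65), but 0 members passed over all genes, and both calls ended with an estimated correlation (adjusted p = 0.699) and with fry (0.514). The estimated version has little power with 4 arrays, so a call lost there decides little. A lower share of hepatocytes would raise the markers of all other cell types alike, but the Kupffer cell median exceeded the mean of the lymphocyte, neutrophil, endothelial, stellate cell and cholangiocyte medians by 0.5053, against a spread over arrays of 0.2288 (SD), which argues against it for the Kupffer cell genes, although neutrophil markers stood at 0.53. A bias with brightness is argued against by both medians lying at percentile 100 of 10000 random lists matched on brightness, whose highest medians were 0.2011 and 0.236. More Kupffer cells, more transcripts per cell, dividing cells of any type, and the genotype itself stay open and untested. Of the 8 splits that part the 4 pairs, 7 could be fitted, and 7 of these, the real one included, gave at least as many shifted lists (real 7, highest other 18), with 8 too few for a share under 0.05 and the other 6 giving medians from −0.91 to 0.60 for cell cycle and −0.42 to 0.68 for Kupffer cell genes, where the sign is arbitrary.

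Wild-type female 2 stood apart from the other females in clock genes. A wrong sex label is argued against by Xist, which was 1.561 log2 units above the lowest other female. A failed hybridisation or labelling is argued against by 43.79% of its spots being well above background, against 42.23% to 43.95% in the other females. Another time of day or feeding state at collection stays open, as 9 of 9 clock genes at the predicted end decides nothing for genes chosen after the pattern was seen, and Nr1d1 and Bhlhe40 were highest in wild-type female 1 (9.04 and 11.02) and not in wild-type female 2 (8.40 and 10.66). Of the 9 genes, Arntl and Npas2 had not passed the filter on dim probes. Collection times are not given in the sources used here, and a biological explanation from the genotype was not tested.

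Genes with small p lay near Pus1 more often than elsewhere. Clusters of such genes anywhere in the genome are argued against by the window around Pus1 lying at percentile 99.69 of 11693 windows centred on tested genes, where neighbouring windows overlap and the highest held 8.63%. Windows centred on the neighbours of Pus1 were not left out and hold many of the same genes. Where the highest window lies was not recorded, so it can be one of these. Donor-strain sequence flanking Pus1 is a candidate explanation. The excess within 20 Mb (two-sided Fisher's exact test, p = 3.85e-12) is the pattern itself, so that test cannot tell donor sequence from an effect of Pus1 loss on its neighbours. The labels state only 5 generations of backcrossing, and the donor strain is not given in the sources used here. Loss of signal from probe mismatch to donor sequence would lower most of these genes, but 8 of 22 were lower, which argues against it as the whole cause. An effect of Pus1 loss on its neighbours stays open and untested.

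Of the 8 splits that part the 4 pairs, 7 could be fitted for genes changed by genotype, and 7 gave at least as many as the real count of 0, which any split must. The highest other count was 1031, with the genotypes of array 4 exchanged, which points to a structure of the samples, although no test parts this from chance agreement of 4 ratios. In that split array 2, which carries wild-type female 2, is the only one of its dye orientation, so the contrast rests on it. For sex, 1 of 3 splits of the 4 arrays, the real one, gave as many as 37 genes (highest other 0), and 1 of 3 gave as many as 17 lists (highest other 9). For the difference of the genotype effect between sexes, 2 of 3 splits could be fitted and 2 gave at least the real count of 0 (highest other 0), again as any must. All these splits are too few for a share under 0.05, and those set against a real count of 0 decide nothing at any number.

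Of 102 groups of 4 values checked, 4 held an outlying value, where chance gives 5.1. The groups were arrays for named genes and lists by genotype, and samples for sex genes and for signal quality. All 4 outlying values were of single arrays. Syt1 had a log2 ratio of −1.487 on array 2, with the others between −0.592 and −0.418. The cytosolic aminoacyl-tRNA synthetases had a median of 0.2328 on array 2, with the others between 0.00815 and 0.0424. The growth hormone and IGF axis had −0.1864 on array 1, with the others between 0.0229 and 0.035, and the Kupffer cell list had 1.117 on array 2, with the others between 0.421 and 0.494.

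The genotype effect differed between the sexes for 11 lists with the preset correlation. An estimated correlation was not run for this test, and in the genotype comparison it ended all 7 calls, in a version with little power. Values are the female and the male median log2 ratio with the adjusted p of the difference. Interferon response had 1.10 and 0.07 (1.39e-24), cholesterol synthesis and uptake −0.30 and 0.31 (2.21e-09) and mitochondrial ribosomal proteins 0.23 and −0.01 (9.07e-06). Kupffer cell markers had 0.81 and 0.43 (2.17e-05), oxidative phosphorylation 0.14 and 0.02 (4.66e-05), and stellate cell genes 0.25 and −0.15 (6.79e-05). The Kupffer cell array medians were 0.49 and 1.12 in females and 0.44 and 0.42 in males, so that difference rests on array 2. The circadian list had −0.40 and 0.17 (0.000132), the endoplasmic reticulum and heat shock list 0.25 and −0.13 (0.00028), and glucocorticoid and feeding responsive genes −0.29 and 0.30 (0.00199). The last of these had array medians of −1.005 and 0.43 in females and 0.43 and 0.16 in males, so its difference rests on array 1. The circadian list had −0.11 and −0.68 in females and −0.11 and 0.45 in males, so arrays 1 and 3 hardly differed and its difference rests on arrays 2 and 4. The endoplasmic reticulum and heat shock list had 0.18 and 0.33 in females and −0.42 and 0.16 in males, so its difference rests on array 3. Female-biased liver genes had 0.13 and 0.04 (0.0159), and the tricarboxylic acid cycle 0.11 and −0.04 (0.0377). The array medians of female-biased genes were 0.02 and 0.23 in females and 0.08 and 0.004 in males, so that difference rests on array 2. Wild-type female 2 is 1 of the 4 samples behind each female median.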

How the results depend on the processing

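Chosen after the data were seen were the additive fit, the sex list alternatives, the lists without genes near Pus1, and the smaller threshold near Pus1 for other windows and left-out arrays. Of 393 alternatives for named genes by genotype besides Pus1, 352 kept their direction and side of the threshold, 39 newly passed and 2 turned direction. Apart from Gpat3 with additive terms, all that newly passed did so in the separate-channel fit with a random block or without replicate 4. The former was too lenient on simulated data, and the latter rests on array 2. The 2 that turned were Tpx2 with no filter on dim probes (−0.07244, from another probe), and Marco (−0.04938) with series table values, where the cause was not tested. For sex 206 of 239 kept both, 27 no longer passed, most with series table values, and 6 newly passed. All 46 values of the difference between sexes kept both, and of 84 list shifts by genotype 67 did and 17 no longer passed.

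Genes changed by genotype numbered 1 (Pus1) with normexp offset 16, median centring, no filter on dim probes or no dye term, 2 (Pus1 and an unnamed transcript) with an intensity trend and robust prior or no replicate block, and 3 with additive terms, which add Gpat3. With the array as a random block in separate channels there were 1514, in a fit that was too lenient on simulated data. Left-out arrays gave 0 to 1490, the latter without replicate 4, where array 2 is the only one of its dye orientation. In the other alternatives the count was 0, with 716 to 2120 at an unadjusted p under 0.05.

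With no replicate block, the pairing by array being dropped, sex gave 3243 genes, against 37. The Pus1 log2 ratio was −2.035 there (adjusted p = 0.0311). It newly passed at −2.568 with offset 16, −2.066 with median centring, and −2.035 with no filter, no dye term, trend and robust prior, and both random-block fits. Left-out arrays gave −2.114 to −1.956.

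Sex genes numbered 6 when well above background in all 8 samples was required, which removes genes silent in 1 sex, 0 with series table values (568 unadjusted), 24 in wild types only (fewer samples), and 65 to 1197 with an array left out. Other alternatives gave 31 to 41.

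List shifts by genotype numbered 0 with an estimated correlation and 0 with fry, 10 to 14 with an array left out and 7 to 9 otherwise. By sex they numbered 0 with an estimated correlation and 18 to 21 with an array left out. Near Pus1, 0 genes passed with any window, and at an unadjusted p under 0.01 there were 22 within 20 Mb, 10 within 10 Mb, 22 on the chromosome, and 6 to 56 within 20 Mb with an array left out (8, 20, 6 and 56, the last with 11.1% of genes elsewhere as well). Leaving out an array left no residual degrees of freedom for the difference between sexes, so it has no value. Signal over background limits ratios of dim genes, Pus1 in mutants among them.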

Other observations

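Other parts of liver metabolism had small genotype ratios that did not pass (camera with the preset correlation). Fatty acid oxidation and PPAR alpha targets had a median log2 ratio of −0.07 (33 tested, adjusted p = 0.621), and fatty acid synthesis and triglyceride storage a median of 0.02 and a mean of −0.03 (26 tested, 0.899). Cholesterol synthesis and uptake had 0.03 (25 tested, 0.747), bile acid synthesis and transport −0.04 (23 tested, 0.362), and gluconeogenesis and glycolysis 0.06 (25 tested, 0.307). The tricarboxylic acid cycle had 0.06 (20 tested, 0.249), xenobiotic metabolism 0.06 (28 tested, 0.122), heme synthesis and iron handling 0.03 (36 tested, 0.362), and coagulation and plasma proteins −0.01 (24 tested, 0.899). Cytosolic ribosomal proteins were lower in mutants in 45 of 58 cases, with a median of −0.07 (0.113).

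Stress and signalling lists did not pass by genotype either. The integrated stress response had a median of 0.07 (25 tested, adjusted p = 0.298), the endoplasmic reticulum and heat shock response 0.01 (20 tested, 0.547), p53 targets and apoptosis 0.06 (15 tested, 0.249) and the acute phase response 0.05 (27 tested, 0.547). The circadian list had −0.37 (17 tested, 0.113), glucocorticoid and feeding responsive genes 0.11 (16 tested, 0.872), and the growth hormone and IGF axis a median of −0.04 and a mean of 0.02 (17 tested, 0.899). Female-biased genes had 0.07 (26 tested, 0.362), male-biased genes 0.04 (32 tested, 0.249), and the Y-linked and X-inactivation list −0.10 (3 tested, 0.249). Red cell and blood genes had −0.12 (11 tested, 0.249), pancreatic acinar genes 0.07 (4 tested, 0.621), adipocyte genes −0.14 (4 tested, 0.491) and genes that diverge between strains 0.03 (6 tested, 0.685).

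Most females also differed from the males in clock genes and Igfbp1, so differences between the sexes cannot be assigned to sex alone. Between the sexes, further lists were higher in females with the preset correlation, and none passed with an estimated one. Their medians, male minus female, and adjusted p were −0.53 for the endoplasmic reticulum and heat shock response (5.38e-05), −0.48 for the tricarboxylic acid cycle (0.00103), −0.49 for amino acid and urea metabolism (0.00225), −0.15 for fatty acid oxidation (0.00581), −0.16 for mitochondrial ribosomal proteins (0.00919) and −0.44 for fatty acid synthesis (0.00919). The integrated stress response had −0.22 (0.0161), gluconeogenesis and glycolysis −0.33 (0.0238), other tRNA modification −0.22 (0.0423) and mitochondrial aminoacyl-tRNA synthetases −0.26 (0.0434). With single arrays left out, 5 of these lists lost the call. Fatty acid oxidation lost it without arrays 2 and 3 (adjusted p = 0.188 and 0.321), fatty acid synthesis without 2 and 4 (0.12 and 0.0663), and mitochondrial ribosomal proteins without 1 and 4 (0.0945 and 0.0577). Other tRNA modification lost it without arrays 2 and 3 (0.192 and 0.0679) and mitochondrial aminoacyl-tRNA synthetases without 2 and 4 (0.18 and 0.109).

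Saa1, an acute phase gene chosen after its values were seen, read 16.6 to 18.0 on the log2 scale in males and 11.9 to 13.0 in females, while the acute phase list did not pass by sex (median 0.35, adjusted p = 0.0616). It passed, higher in males, with any single array left out (5.21e-13, 8.6e-07, 1.34e-15 and 4.82e-08 without arrays 1 to 4). Across genes, which are not independent replicates, centred levels of wild-type female 2 correlated with those of the other samples at r from −0.269 to −0.0546.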
